A study of Arabidopsis thaliana with 4 samples.

How the data were processed

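H3K27me3 chromatin immunoprecipitates and input DNA from Arabidopsis thaliana Col-0 seedlings were compared on 2-colour tiling arrays. Per the labels, each of 2 immunoprecipitations (I and II) was labelled directly after amplification and hybridised against its own input on 2 arrays, with the immunoprecipitate in Cy5 on one and in Cy3 on the other. The antibody was a commercial one against H3K27me3. All 4 arrays form 1 group.

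The deposited values are a score per probe that behaves as a log ratio. The authors' normalization, background correction, log base, centring and direction are not given in the sources used here, and the array design, scanner settings and probe positions were not used here. The column medians of the deposited score were -0.94 (replicate I) and -1.20 (replicate II), so the values are not centred on 0. The ranges were -2.80 to 3.47 and -2.53 to 3.51. Both arrays of a dye exchange hold the same deposited score for all 21740 probes, with a largest difference of 0. The authors thus gave 1 value per dye exchange, which removes any view of dye effects and of the spread between the 2 arrays. Of the 60 features without a value, 39 are control spots and 21 are plate and well probes, 15 of these on plate TC 25. No per-sample column was left unused.

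The 2 arrays of a dye exchange were averaged to 1 replicate, and each replicate was centred on its median. The median lies above the mode of the array, by 0.31 units in replicate I and 0.19 in replicate II. The test was limma's lmFit and eBayes with an intercept only, two-sided, with Benjamini-Hochberg adjustment at 0.05 over 21740 probes. It leaves 1 residual degree of freedom per probe, so that most of the variance estimate comes from the other probes. A rule of size was used beside it: an upper probe lies at least 1 unit above the median in both replicates. Neighbouring probes are correlated, so counts of calls are not counts of independent events. Before the data were examined the test, the rule of size, the shuffles of neighbours and the list of alternatives were fixed, except where a choice is said to be later. The runs, the stretches and their tests were chosen after the data were seen. The plan had been written for log2 values, and the rule had been meant as 2-fold; as the log base is unknown, it is applied as 1 unit.

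Neighbours were probes in consecutive wells of the same series (TA, TB, TC, TD or PD), counted plate by plate in rows of 12 wells and 96 wells per plate. Runs are unbroken sets of upper probes in consecutive wells. Stretches without an upper probe may span missing wells. Intervals are 95% percentile intervals of 1000 bootstraps over plates, except that 500 were drawn for the ratio of spreads and that the interval across plate boundaries resampled the boundaries. They describe the variation over plates of these 2 replicates, not over seedlings. The bootstrap over plates treats plates as independent, although stretches without an upper probe span many plates, so the intervals may be too narrow. The share of neighbours was tested against 1000 shuffles of the calls, and the longest stretch against 1000 random placements of the same runs.

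The rule for named probes was the 10 highest and 5 lowest by mean among probes past the test with the same sign in both replicates. As probes are not paired with genes here, 2 of each side are named. Gene lists and chromosome regions had been fixed for the case that probes could be placed. No list could be applied. The region limits were used only in a test under an assumed probe order, among the closing observations.

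The limma step was tested on simulated data: noise was drawn from the variance prior fitted to the 2 replicates, and shifts were planted among 21740 probes. With 4000 planted probes, 21.6% of shifts of 0.5 units, 93.4% of shifts of 1 unit and 100% of shifts of 2 units were recovered, with 200 false calls. With 200 planted probes, 4.0% of shifts of 1 unit and 96.0% of shifts of 2 units were recovered, with 5 false calls. The simulated noise was independent between probes, and both replicates had the same scale. In the data neighbouring probes are correlated and the replicates differ in scale, so these rates do not carry over to the data. The neighbour step was tested on 21740 simulated calls with a planted share of 75% followed by another call, and it gave 74.9%.

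The alternatives tried were no centring, centring on the mode, equal spread of the replicates, quantile normalization, a stricter threshold, a minimum of 1 unit, a trended and robust variance prior, and a 2-component normal mixture. The sign turned, the array without the PD probes, rules of 0.5 and 1.5 units, neighbours among the limma calls and the rule of size in each replicate alone were added after the data were seen. The software was R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0 and matplotlib 3.10.9.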

Results

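Chromatin immunoprecipitation with an antibody against trimethylated lysine 27 of histone H3 (H3K27me3) was hybridised against input DNA on a tiling array. How much of the genome the array covers was not examined here. H3K27me3 is the mark set by Polycomb repressive complex 2, and in plants it lies on many developmentally silenced genes. The material was 10-day Columbia (Col-0) seedlings of Arabidopsis thaliana grown in liquid medium without treatment, a wild-type reference for mapping the mark. All samples form 1 group, immunoprecipitate against input, with 2 immunoprecipitations, here called replicates I and II. Each was hybridised on 2 arrays with the dyes exchanged, which makes 4 arrays. The labels do not say whether replicates I and II came from separate cultures, so the spread between them may be technical.

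The deposited table lists 21800 features, of which 21740 carry a value on all 4 arrays. The 2 arrays of each dye exchange hold identical values for all 21740 probes, so there is 1 value per replicate and n = 2 throughout. The values behave as a log ratio, but their log base and direction are not stated, so they are given in units of the deposited scale. The likely direction is immunoprecipitate over input. Its only basis is that a minority of probes forms a long tail on the high side. The identical values of a dye-exchanged pair show that both arrays run the same way, but not which way. With the sign turned, every statement about upper probes becomes one about lower probes. The deposited medians were -0.94 in replicate I and -1.20 in replicate II, and values below are relative to these medians unless named as deposited. Single intensities are not used here, so the precision of a value rests on the agreement of 2 replicates. Probes are named by plate and well and are not paired with genes or positions, so no gene is named and no planned comparison of genes, gene lists or placed regions was made.

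The first comparison asks which probes stood apart from the bulk of the array in both immunoprecipitations. H3K27me3 values formed a dense lower population and an extended upper tail. In all, 3524 of 21740 probes (16.2%, 95% plate bootstrap interval 14.6 to 18.0%) lay at least 1 unit above the median in both replicates. These are called upper probes, and 1 unit is 2-fold if the scale is base 2. The number depends on the rule and the centring: 5571 probes passed at 0.5 units, 2169 at 1.5 units, and 833 at 1 unit with the values left as deposited. On the opposite side only 10 probes lay at least 1 unit below the median in both. Upper probes averaged 2.41 units in replicate I and 1.78 units in replicate II.

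The replicates ranked probes alike. Across the 21740 probes, which are not independent replicates, Pearson's r was 0.932 (95% plate bootstrap interval 0.927 to 0.938) and Spearman's rho was 0.844. Within the 3524 upper probes r was 0.858, and within the other 18216 probes it was 0.775. Replicate I had 5183 probes at 1 unit or more and replicate II had 3724. Of the probes that passed in replicate II, 94.6% passed in replicate I, whereas 68.0% of those in replicate I passed in replicate II. Independent lists of these lengths would share 888 probes. Replicate I was the higher of the 2 for 97.8% of the upper probes. The least-squares slope of replicate II on replicate I was 0.71. The SD between the 2 replicate values, pooled over probes, was 0.273 units outside the upper group and 0.496 units for upper probes. For upper probes most of it was the mean offset of 0.625 units between the replicates, and without that offset the SD was 0.226 units.

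**Figure D1:**
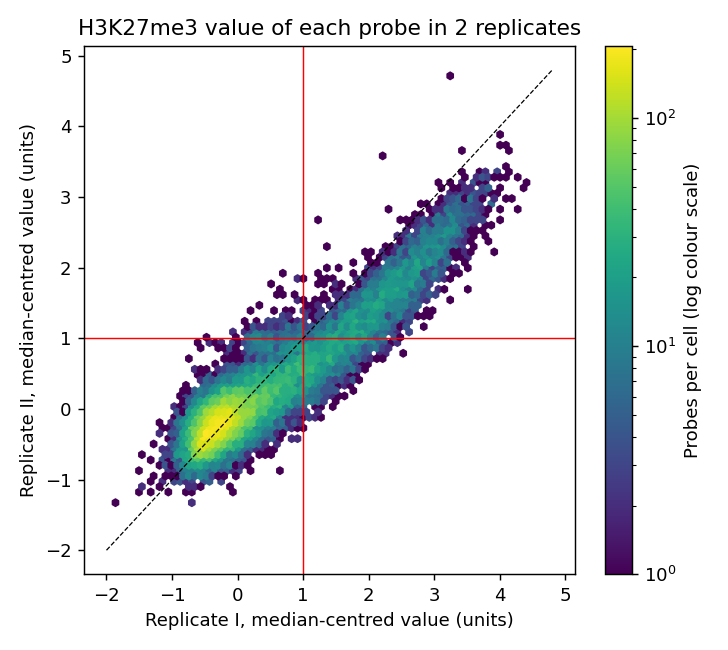
Median-centred value of each of the 21740 probes in replicate I (x axis) and replicate II (y axis), in units of the deposited scale; colour gives the number of probes per cell on a log scale. Red lines mark 1 unit, the dashed line marks equal values, and the upper tail runs below it, with 3524 probes past 1 unit in both.

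In limma's moderated test on the 2 replicate values, 5897 probes (27.1%) were above the array median and 1046 (4.81%) below it at a Benjamini-Hochberg adjusted p under 0.05. The remaining 14797 probes did not pass. The mean of the probes called above was at least 0.57 units, and the median of their means was 1.52. All 3524 upper probes were among the 5897. The split between the sides depended on the scaling and on the variance prior. Calls above made up 84.9% of all calls after median centring, 99.5% after centring on the mode, 65.9% after equalising the spread of the replicates and 14.4% with the values left as deposited. The lower calls numbered 37, 3666 and 14914 in the last 3 of these settings. With a trended and robust variance prior they numbered 5147, and calls above made up 54.0%. Beyond the lowest probes named next, only the upper side is therefore described. The test has 1 residual degree of freedom and borrows its variance across probes.

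The highest probe by mean past the test was TB40E11, at 3.28 units in replicate I and 4.72 in replicate II (SD 1.02, n = 2, limma adjusted p = 0.000358). Its rank rests on replicate II, as its value in replicate I lay below the 99th percentile of that replicate (3.39 units). TB04E05 followed, at 4.01 and 3.91 units (SD 0.07, n = 2; limma adjusted p = 0.000313). TB04E05 lay in a run of 16 neighbouring upper probes and TB40E11 in a run of 6. On the lower side the number of calls depended on the scaling and on the variance prior. The lowest probe was TA53H07, at -1.86 and -1.28 units (mean -1.57 ± 0.41, SD, n = 2, limma adjusted p = 0.00171). TB81A05 was next, at -1.50 and -1.20 units (mean -1.35 ± 0.21, SD, n = 2; limma adjusted p = 0.00190).

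The second comparison asks whether upper probes lie together. The order used is that of the names, plate by plate, row A to row H and wells 1 to 12 within a row; whether this is their order in the genome is not stated in the sources used here. Upper probes were strongly clustered in this order. An upper probe was followed by another in 73.7% of 3520 cases (95% plate bootstrap interval 71.7 to 75.7%), against 5.10% after any other probe. In 1000 shuffles of the calls the share never exceeded 17.9% (permutation p = 0.001, one-sided, the smallest that 1000 shuffles can give). Neighbouring values correlated at r = 0.836 in replicate I and 0.793 in replicate II. The correlation of a probe in 1 replicate with its neighbour in the other, which shares no noise of a single array, was 0.793. It fell to 0.401 at 5 wells, 0.237 at 12 wells and 0.094 at 96 wells. A bias of neighbouring wells that repeats on all arrays would stay in this correlation.

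**Figure D2:**
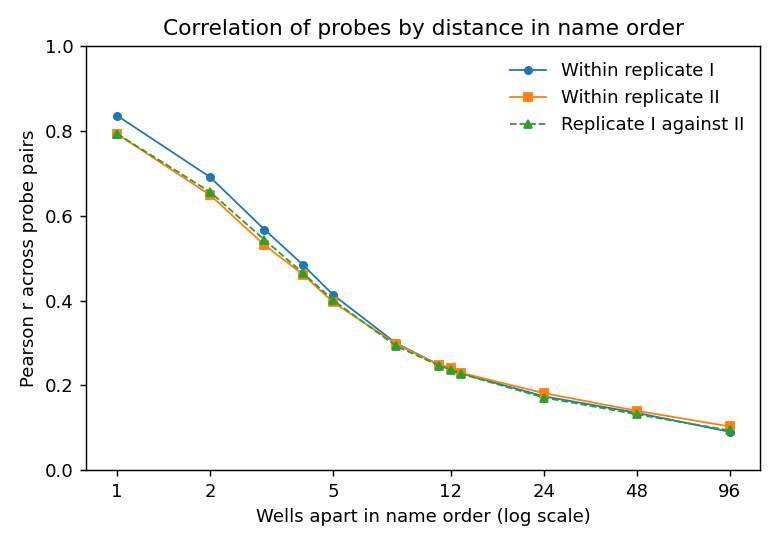
Pearson correlation across pairs of probes (y axis) against their distance in wells in name order (x axis, log scale), within replicate I, within replicate II and between a probe in 1 replicate and its neighbour in the other. All 3 curves fall from about 0.8 at 1 well to about 0.1 at 96 wells.

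The 3524 upper probes formed 929 runs of consecutive wells, with a median of 3 probes and a mean of 3.79. Single probes made up 264 runs, which held 7.49% of the upper probes. A further 416 runs had 2 to 4 probes, 191 had 5 to 9, and 58 had 10 or more. Runs of 5 or more held 59.4% of the upper probes. In 100 shuffles the mean number of runs was 2956, the longest had 8 probes, and at most 7 runs reached 5 probes, against the 249 observed. The longest run covered 46 probes of plate TB 32 with a mean of 2.07 units. The next had 36 probes across plates TB 24 and 25 (mean 1.94 units) and 28 probes on plate TB 38 (mean 2.60 units).

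The height of runs was set beside their length as a description. To keep the noise that defines a run apart from its height, runs were defined in replicate I alone and their height was read in replicate II. The mean height was 0.80 ± 0.46 units (SD over 354 runs) for single probes and 1.07 ± 0.42 for the 476 runs of 2 to 4. It was 1.48 ± 0.38 for the 244 runs of 5 to 9 and 1.68 ± 0.38 for the 120 runs of 10 or more. Runs of the same arrays are not independent replicates, and as neighbouring probes are correlated, a longer stretch above a fixed rule is higher by construction, so a test against no relation would be void.

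Probes between upper probes were mostly upper too. Of 2088 probes with an upper probe on both sides, 92.4% were themselves upper, and 6 lay below 0.5 units in both replicates. Clustering alone makes this share high and no expected share was computed, so it does not show whether runs were interrupted seldom or often. Single upper probes were not rare, with 264 runs of 1, but few stood among low ones. Only 4 had both neighbours below the median in both replicates, with means of 1.57 units in replicate I and 1.23 in replicate II. As neighbouring values are correlated, such probes would be few in any case, and no expected number was computed.

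The third comparison asks how the upper probes spread over the array's probe series. The share of upper probes was 15.9% over the 99 TA plates (95% plate bootstrap interval 13.1 to 18.9%) and 18.3% over the 100 TB plates (15.9 to 20.9%). It was 7.75% over the 27 TC plates (3.55 to 12.1%), 9.38% on the only TD plate and 30.1% over the 4 PD plates, for which no interval was computed. The TC plates fell into a part with upper probes and a part nearly without them. Plates up to number 12 held 185 upper probes of 1248 (14.8%), and plates from 13 on held 1 of 1152 (0.0868%). That limit was set after the values were seen.

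Upper probes varied widely between plates, with a median of 14.6%. Of 231 plates, 32 held none and 6 held more than 50%. The fullest was plate TA 97, where 86 of 96 probes were upper (89.6%) and the medians were 2.85 units in replicate I and 2.05 in replicate II. Plate TB 21 followed with 63.5% and plate TB 25 with 62.5%.

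The 2 longest stretches without any upper probe were longer than random placement gave. The longest ran over 966 probes of plates TC 18 to 30. No probe between plates TC 25 and TC 27 carries a value, and plates TC 25, 28 and 30 are incomplete. The second ran over 759 probes of plates TA 37 to 46, of which TA 38 and 39 are incomplete. The next ran over 359 probes of plates TA 21 to 25. When the same runs were placed at random within each series 1000 times, the longest stretch was at most 390 probes (permutation p = 0.001, one-sided, the smallest that 1000 placements can give). Within the first 2 stretches (1725 probes) the median was -0.48 units in replicate I and -0.44 in replicate II. It was -0.09 and -0.06 for the other probes outside the upper group. Part of this difference follows from the selection, as the stretches were chosen for holding no upper probe and the other probes include those beside runs. The mode of the whole array lay at -0.31 units in replicate I and -0.19 in replicate II. At a rule of 0.5 units the longest stretch was 293 probes, and no placement test was run at that rule.

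**Figure D3:**
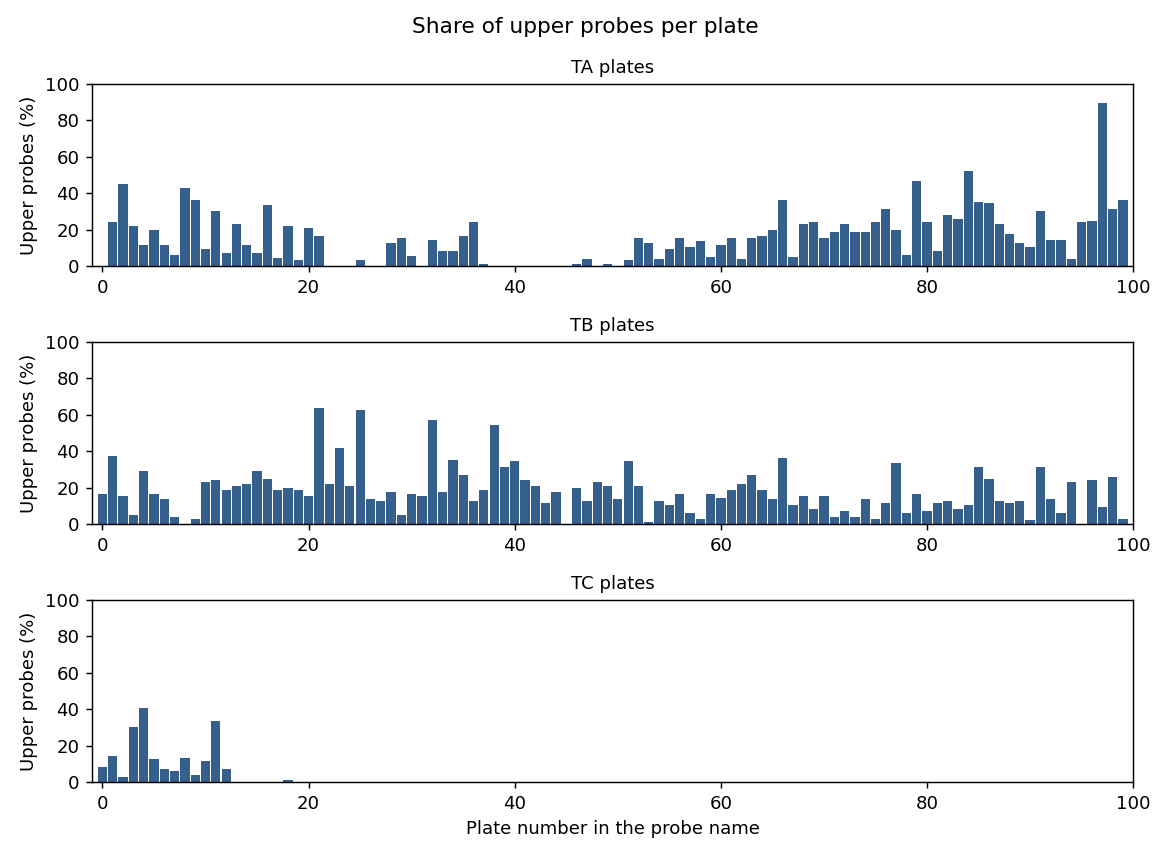
Share of upper probes (y axis, percent of the probes on a plate) against the plate number in the probe name (x axis) for the TA, TB and TC plates. Plate TA 97 stands at 89.6%, and stretches with almost none span plates TA 37 to 46 and TC 18 to 30. No TC plate has a number above 30. No probe between plates TC 13 and TC 17 or between TC 25 and TC 27 carries a value, and these gaps look like plates at 0%.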

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

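The 5897 probes called above the median were within 1.5 times that number in every setting fixed beforehand but no centring, which gave 2518. The others gave 4297 (adjusted p under 0.01) to 7220 (quantile normalization), and 5120 with the mixture, of which 5097 were among the 5897. Of the main calls, 5897 remained after mode centring, spread scaling and quantile normalization. The 1046 probes called below the median had no stable number: 14914 without centring, 37 with mode centring, 3666 with spread scaling, 4049 with quantile normalization, 46 at adjusted p under 0.01, 19 with a minimum of 1 unit and 5147 with the trended, robust prior. Turning the sign, chosen after seeing the data, exchanges the sides (1046 above, 5897 below) and leaves 10 probes past 1 unit in both replicates. The 3524 upper probes became 833 without centring, 5571 at 0.5 units and 2169 at 1.5 units. The share of upper probes followed by another (73.7%) was 54.6% without centring, 76.0% at 0.5 units, 67.3% at 1.5 units and 77.4% with the limma calls, and 71.8 to 77.1% with 1 replicate left out. The correlation of the replicates (0.932) was 0.935 after quantile normalization and 0.932 without the PD probes; a shift or a scale factor per replicate cannot change it. The longest stretch without an upper probe was 966 probes, 293 at 0.5 units and 1183 at 1.5 units. As centring sets what counts as 0, the moves under no centring and mode centring follow from their construction. So do the counts with the sign turned and under other thresholds or rules of size, which change the side or the cutoff itself. The cause of the other moves was not tested.

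Without a replicate, limma has no residual degrees of freedom, so that setting has no test. The fits by dye orientation, the fit of 4 arrays with a dye term and the filter on missing probes were not run, because the arrays of a dye exchange hold identical values and the same probes are empty on all 4. The settings for genes, gene lists and regions were not run, because probes are not placed here; region limits entered only 1 test under an assumed order, given under the other observations. Signal over background is not used here, so dim probes cannot be set apart.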

Other observations

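The tests of plate position, of the spread ratio and of the windows were chosen after the result was seen; the tests of plate boundaries, of failed spots and of the incomplete plates were written before their values.

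The similarity of neighbouring probes was not explained by a shared plate column or by a level per plate. A bias shared by neighbouring wells on all arrays was not tested. If probes handled together in a plate column were alike, the correlation 12 wells apart would stand above that at 11 and 13 wells. The excess was 0.00143 (95% interval -0.00124 to 0.00420). If a plate had a level of its own, neighbours across a plate boundary would be less alike. Their correlation was 0.837 over 220 boundaries and 0.835 within plates, a drop of -0.00283 (interval -0.0517 to 0.0647). A candidate explanation is that names follow genomic order and that the mark covers blocks of several probes; DNA fragments longer than a probe stay open, as neither probe nor fragment lengths are used here.

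Replicate II spans a narrower range than replicate I, but not by 1 common factor. The distance from the median in replicate II over that in replicate I was 0.94 at the 5th percentile and 0.84 at the 25th. It was 0.65 at the 75th, 0.75 at the 95th and 0.81 at the 99th, so it was lowest on the shoulder above the median. The difference between the 5th and 95th percentiles was 0.193 (interval 0.145 to 0.249), where a common factor would give 0. With 2 replicates and no separate channels, neither the enrichment of the immunoprecipitates nor the authors' processing was tested as the reason.

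The 2 stretches longer than any random placement carried reproducible values. Within them the replicates correlated at r = 0.655 (interval 0.561 to 0.740), and neighbours at 0.435. Values that vary at random from spot to spot and array to array would give correlations near 0. Both replicates were read on the same probes, so weak spots with a bias that repeats between arrays were not excluded. The SD between the replicate values was 0.183 units inside and 0.281 in the other probes outside the upper group. A hypothesis is that the long stretches on the TA plates are the heterochromatic knob and the pericentromere of chromosome 4, which are poor in this mark, if the TA and then the TB probes tile that chromosome in name order. No label states this. Limits of 1.6 to 2.4 Mb and 2.8 to 5.2 Mb, approximate and set before the data were examined, fall on plates TA 18 to 27 and TA 31 to 57 when scaled by length. They held 6.29% upper probes against 19.3% elsewhere on the TA and TB plates, and 3.91% of 946 windows moved along the order held as few. The windows were moved in steps of 20 probes and overlap strongly. They amount to few independent positions, so this share is not a p-value. The result goes with the hypothesis but rests on the assumed order and on the likely direction of the score. It leaves the TC stretch unaccounted for, and repeated sequence that hybridises at many loci stays open for both.

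Probes missing from the TA plates gave a negative result. The 13 TA plates counted as incomplete all lie between plates TA 17 and 39, and lack 170 wells. Plates TA 4, 30, 34 and 90 also have wells without a value but were not counted as incomplete. The 13 plates held 5.19% upper probes and the other TA plates 17.3%. Among 99 circular shifts of the TA plates, 13.1% gave as low a share, so chance placement along their order was not excluded. The TC plates were not tested in this way. Their incomplete plates TC 13, 17, 25, 28 and 30 held no upper probe, but nearly all full TC plates from 13 on held none either.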
